A study of Saccharomyces cerevisiae with 58 samples.

How the data were processed

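RNA of budding yeast was measured on 58 Affymetrix arrays, each a single time point of a single culture. Per the labels, 28 arrays came from a wild-type strain and 30 from a strain that carries disruptions of CLB1, CLB2, CLB3, CLB4, CLB5 and CLB6, the genes of the B-type cyclins, together with a construct in which the GAL1 promoter drives CLB1. Per the labels' protocols, early G1 cells were collected by elutriation, which sorts cells by size, and were released into dextrose medium with sorbitol. The series design states 2 biological replicates per strain, and the replicate in the comparisons of level, dynamic range and period was therefore the culture (n = 2 per strain), while the periodicity and interaction tests were fitted over arrays. The cultures were sampled on 2 grids of times. Wild-type culture 1 and mutant culture 2 ran from 30 to 254 min, and wild-type culture 2 and mutant culture 1 from 38 to 262 min.

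The deposited values are linear intensities of probe sets, from 86.1 to 33787. The authors used affy 1.8.1, per the submitters' processing notes. The method of background correction, summary and scaling between arrays is not given in the sources used here. Mean intensity per array lay between 2067 and 2121, so the arrays share a common scale as deposited. All tests were run on log2(intensity + 1), and differences are on that scale. With a lowest intensity of 86.1 the added 1 changes little, but background signal can understate changes of dim probe sets. With 2 cultures per strain the precision of the level, dynamic range and period comparisons is low, and no count or read depth exists for these data.

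The table holds 10928 probe sets, of which 7245 are in the platform's gene name table. 5498 were named to a gene of the S. cerevisiae R64 annotation and gave 5449 genes. For the 47 genes with more than 1 probe set the brightest was used, and in 0 of the 47 did the probe sets differ by more than 1 log2 unit in the strain difference. 12 symbols were updated through their Entrez number. A further 1747 named probe sets belong to genes outside that annotation and served as cross-hybridisation background. Their 95th percentile was 9.06 (log2), and 4853 genes lay above it on average. 3683 probe sets had no gene name here, among them 166 control and 47 reporter probe sets, and 1 had several symbols. 128 of the named probe sets carry a suffix that marks probes shared between similar transcripts. No genome sequence was used here, so no coordinates are given and the annotation served only for names and neighbours. The positions of probes within genes were not analysed here. TRP1 has no named probe set in the table used here and is left out.

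Analyses used R 4.3.3 with limma 3.58.1 and splines 4.3.3. For the level comparison, each culture was averaged over its arrays at times that both strains shared on its grid (56 arrays, with 2 mutant arrays left out), and the 4 culture means were fitted with limma. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference between strains was also fitted for the times up to 142 min and after 142 min, and the change between these parts was tested with limma on the culture means. Periodic genes were found in each strain with limma's F-test of a cosine and a sine term beside culture and linear time. They were called at an adjusted p under 0.05 and a fitted peak-to-trough of at least 1.5-fold. The period was the value between 60 and 160 min with the largest median partial R2 over the G1/S genes of that strain. Arrays within a culture form a time series, and the F-tests over arrays treat them as independent given the model, which can make these p-values too small. Dynamic range was the log2 of the SD over time of a culture after removal of a linear trend. A strain by time interaction was tested with natural cubic splines of 8 degrees of freedom.

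A total of 24 gene lists were fixed before the data were examined, 7 of cell cycle genes and 17 of other kinds, including lists of a-specific, alpha-specific and meiotic genes as markers of other cell types. 1 of the cell cycle lists was tested with the rest and is not reported here. They were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The genes named in the text also follow a rule fixed at that time. They are the targeted genes and the genes in the strain labels, the 10 largest rises and falls in level whose cultures did not overlap, the 3 most strongly periodic members of each cell cycle list, the 10 largest peak-to-trough values per strain, the 10 largest changes in dynamic range, a fixed set of regulators, and up to 4 leading members of each called list. Neighbours of targeted genes and a few genes stated as such were added after their values were seen.

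The level, periodicity, dynamic range and interaction steps were tested on simulated data made from the mean and spread of each real gene. Noise was independent between arrays apart from a shift per culture, and no early change or time trend was simulated. The recovered shares therefore do not cover these features of the real arrays. In the level comparison over 5449 genes, 25.4% of genes changed by 0.5 log2 units were recovered, 71.6% at 1 and 93.9% at 2, with 4 false calls among 5249 unchanged genes. For periodic genes, 11.9% were recovered at a peak-to-trough of 0.5, below the fold rule, and 100.0% at 1 and at 2. The simulated period was 100 min in both strains and was found on the simulated periodic genes themselves. For dynamic range and the interaction, a wave with these peak-to-trough sizes was put into the wild type alone, against a flat mutant. These sizes are not log2 ratios of SD over time. For dynamic range the shares were 44.8%, 86.6% and 100.0%, and for the interaction 70.1%, 91.0% and 100.0%. False calls were 0 of 5049 unchanged genes for periodicity, 1 of 5249 for dynamic range and 11 of 5249 for the interaction. Alternatives tried were quantile normalisation, median centring of arrays, a filter on dim genes, a pseudocount of 16, the mean over probe sets, each culture left out, replicate number or sampling grid as a block, culture as a random block, other periods, harmonics and thresholds, other spline and trend settings, and an estimated inter-gene correlation. After the data were seen, fits without the arrays before 62 min and without 2 arrays of outlying background were added.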

Results

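The series asked which part of the transcription programme of the yeast cell cycle continues in cells without the B-type cyclins. Transcript levels were followed over time in 2 wild-type cultures (14 arrays each) and 2 cultures of the B-cyclin mutant (15 arrays each) after release of elutriated early G1 cells. Values were probe set intensities on a log2 scale for 5449 genes. The median log2 value over the genes lay between 10.79 and 10.92 on all arrays. Neighbouring arrays of a culture correlated at 0.976 to 0.999 from 62 min on and at 0.899 to 0.983 before that, so the earliest arrays stood apart from the rest in both strains.

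The targeted genes were examined first. CLB2, CLB3 and CLB4, which encode mitotic B-type cyclins, lay below the background level of 9.06 on 30 of 30 mutant arrays. Their mutant-minus-wild-type differences were -2.35 ± 0.08 (SE, n = 2 cultures per strain) for CLB2, -3.04 ± 0.08 for CLB3 and -2.15 ± 0.08 for CLB4, with adjusted p values of 2.1e-05, 9.0e-06 and 2.1e-05 (limma). With mutant values at background, these sizes are lower bounds on the loss. CLB1 was higher in the mutant by 1.31 ± 0.08 (adjusted p = 0.00022). It stayed between 11.11 and 11.98 on the mutant arrays, while in the wild type it ranged from 7.93 to 12.06 with its highest value at 134 min. The S-phase cyclin genes CLB5 and CLB6 kept signal above background on the mutant arrays. CLB5 was higher by 1.03 ± 0.14 (adjusted p = 0.0063) and CLB6 was lower by -0.81 ± 0.09 (adjusted p = 0.0025). A probe set outside a disrupted part of a gene does not check the disruption. The CLB1 probe set may also read the GAL1-driven copy, which was not settled here.

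The other measured genes taken from the strain labels were higher in the mutant over the whole course. URA3 rose by 1.36, ARG4 by 1.38, HIS2 by 1.19, LEU2 by 0.67 and APE1 by 0.58, with adjusted p values from 0.00022 to 0.0086. The rise of URA3 did not hold for all its parts. Control probe sets for its 3′ and middle parts were higher in the mutant (1.42 and 1.30), and that for its 5′ part was lower (-0.47, limma adjusted p = 0.04). The APE1 difference was -0.15 over the times up to 142 min and 1.39 after them. GAL1, which encodes galactokinase, rose by 1.59 ± 0.08 (adjusted p = 0.0001). BAR1, the protease that degrades alpha-factor, rose by 2.40 ± 0.08 (adjusted p = 2.1e-05). The wild-type label lists bar1 and the mutant label does not. BAR1, SNL1 and YIL014C-A were the only 3 genes below background on all wild-type arrays and above it on all mutant arrays, and these 3 genes are adjacent in the annotation. CLB3 and CLB4 were the only 2 genes with the opposite pattern.

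**Figure D1:**
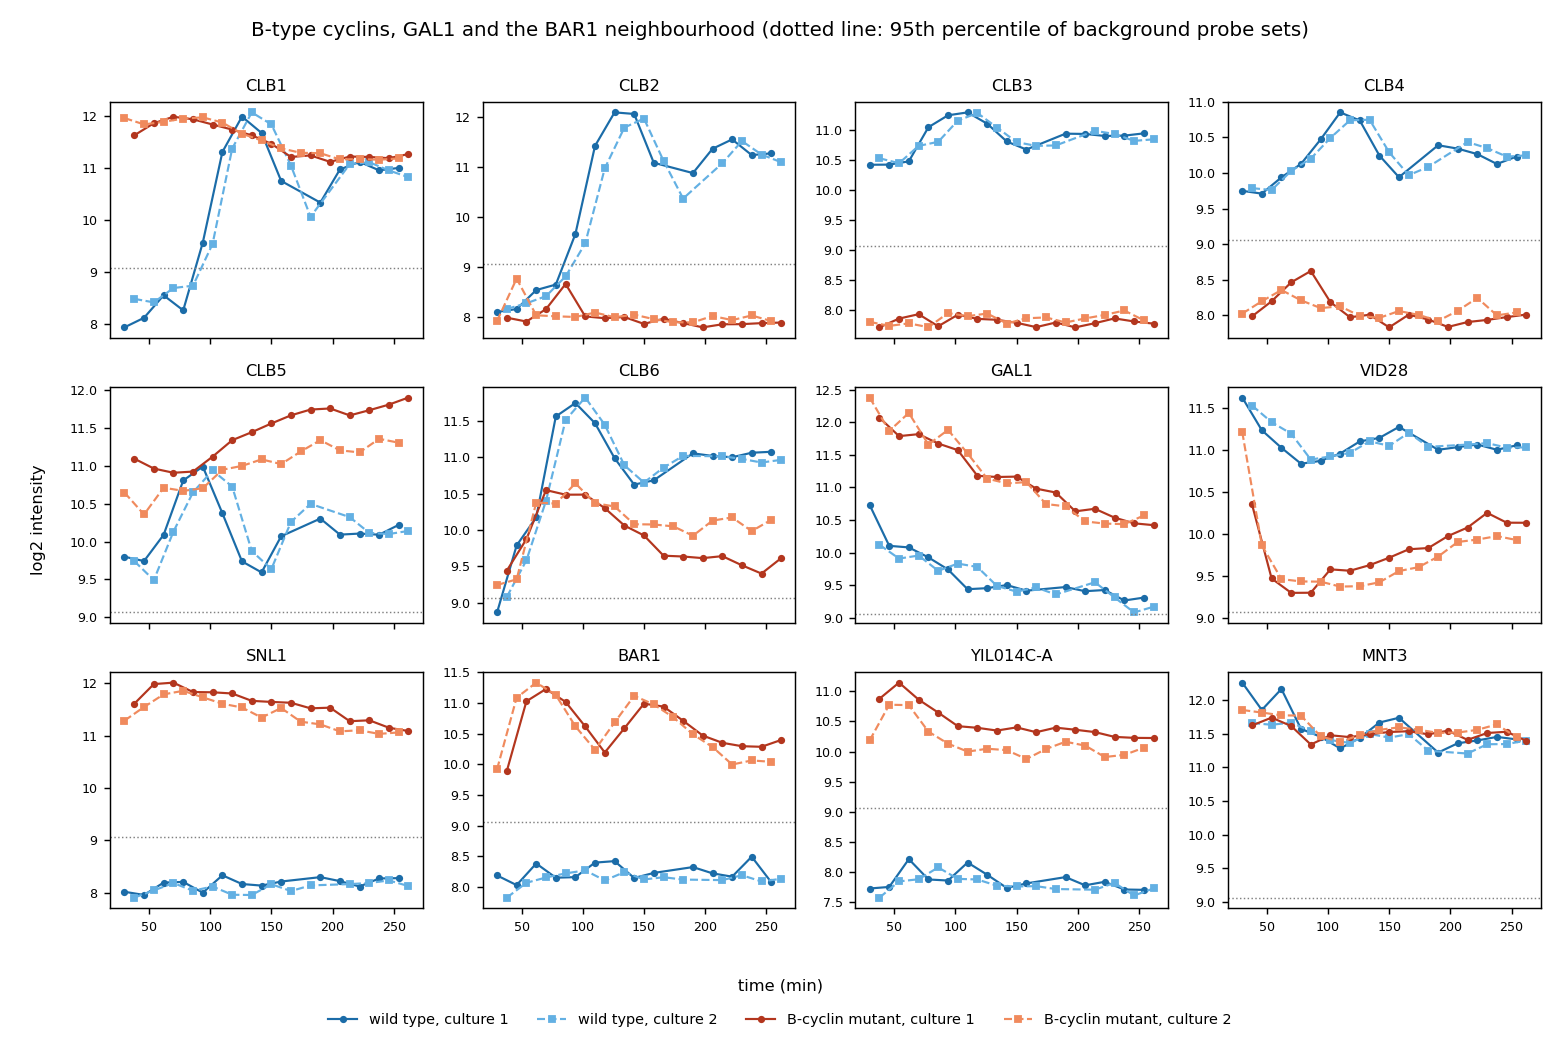
Log2 intensity against time in minutes for the B-type cyclin genes, GAL1, and BAR1 with its neighbours SNL1, YIL014C-A, VID28 and MNT3; lines join the arrays of a culture and the dotted line marks the background level of 9.06. CLB2, CLB3 and CLB4 lie under the line on all 30 mutant arrays, and BAR1, SNL1 and YIL014C-A lie under it on all 28 wild-type arrays.

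Over the whole course, most measured genes of the CLB2 cluster and of the Mcm1 list were lower in the mutant, and some G1/S genes, among them G1 cyclin genes, were higher. The calls of whole lists hold at the preset correlation and were lost with an estimated correlation. Where the count of a list is given in a single direction, no member passed the threshold in the other. In the CLB2 cluster of G2/M genes, 14 of 21 measured members fell (median -0.58), or 16 fell and 1 rose when adjusted over the list alone. HOF1, a cytokinesis protein, fell by 1.88, MMR1 by 1.24, and CDC20, an activator of the anaphase-promoting complex, by 1.07. Among the 9 genes of the Mcm1 early cell cycle box, 7 fell (median -0.72; 8 fell adjusted over the list alone). The helicase gene MCM7 fell by 1.58 and the G1 cyclin gene CLN3 fell by 0.73.

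In the list of G1/S genes of budding, cell wall and regulation, 10 of 24 rose and 1 fell (median 0.27; 15 rose and 1 fell adjusted over the list alone). The G1 cyclin genes CLN1, PCL1 and CLN2 rose by 0.98, 0.87 and 0.87. In the S phase and spindle list, 6 of 13 rose (median 0.33; 7 rose adjusted over the list alone), led by SPC98, a component of the spindle pole, at 0.70. The G1/S replication and repair list was not called (3 of 28 rose, median 0.06, adjusted p = 0.101), nor was the histone list of 7 core histones and the linker histone HHO1 (median 0.07, adjusted p = 0.462), in which HHO1 alone rose, by 0.50. By camera the adjusted p was 3.8e-13 for the CLB2 cluster, 2.1e-08 for the Mcm1 list, 8.5e-05 for the budding list and 0.0113 for the S phase list. With an estimated correlation 0 of the 24 lists were called by camera, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.282 with an estimated correlation.

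Outside the cell cycle, the environmental stress list rose in 11 of 20 members and fell in 1 (median 0.48, camera adjusted p = 2.1e-07; 13 rose and 1 fell adjusted over the list alone). The small heat shock protein genes HSP42 and HSP12 rose by 1.05 and 0.87, and YGP1, a secreted glycoprotein, fell by 1.67. Heat shock chaperones rose in 6 of 14 members (median 0.26, adjusted p = 0.00013; 6 adjusted over the list alone), led by HSP104 at 0.63. The galactose regulon rose in 6 of 8 members (median 0.55, adjusted p = 2.7e-06; 6 adjusted over the list alone), with GAL10 at 1.64 and GAL7 at 1.13. Sulfur assimilation genes rose in 5 of 18 members (median 0.30, adjusted p = 0.0127; 9 rose and 1 fell adjusted over the list alone), led by MET17 at 0.85. Of the 7 a-specific genes, 5 fell and 1 rose (median -0.94, adjusted p = 3.2e-05; 6 fell and 1 rose adjusted over the list alone). The a-factor genes MFA2 and MFA1 fell by 1.98 and 1.14, and the member that rose was BAR1. The iron regulon fell in 3 of 13 members (median -0.26, adjusted p = 0.00027; 6 fell adjusted over the list alone), and ribosome biogenesis genes fell in 2 of 29 (median -0.04, adjusted p = 0.0421; 2 fell adjusted over the list alone). With an estimated correlation the adjusted p was 0.282 for the galactose, a-specific, iron and stress lists, 0.458 for sulfur assimilation, and 0.494 for the chaperones and ribosome biogenesis.

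The other lists were not called by camera. Their medians were -0.22 for alpha-specific genes (adjusted p = 0.214), -0.06 for meiosis and sporulation (0.462), 0.07 for the phosphate regulon (0.789), -0.02 for pheromone-induced genes (0.758) and -0.14 for glucose-repressed genes (0.159). They were -0.01 for single-copy ribosomal proteins (0.619), 0.10 for amino acid biosynthesis (0.226), -0.08 for mitochondrial respiration (0.0516), 0.39 for cell wall stress (0.108) and 0.08 for DNA damage inducible genes (0.476).

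Across all 5449 genes, 310 were higher and 276 lower in the mutant (limma, adjusted p under 0.05). In a joint limma fit of the genes with the background probe sets, 0 of the 1747 background probe sets were higher and 6 lower (2 and 121 at an unadjusted p under 0.05), a share of 0.343% against 9.18% of the genes in that fit. The largest measured rises were SNL1 (3.38), UBC13, a ubiquitin-conjugating enzyme of DNA repair (2.56), YIL014C-A (2.51), BAR1, the hexose transporter gene HXT2 (1.79), GAL10, GAL1, TIR3 (1.53), GPM2 (1.39) and ARG4. The largest falls were CLB3, CLB2, CLB4, MFA2, HOF1, DSE4 (-1.84), QDR2 (-1.80), YGP1, YMR030W-A (-1.65) and MCM7. The wild type averaged below background for SNL1, YIL014C-A, BAR1 and GPM2, and the mutant for CLB3, CLB2, CLB4, HOF1, DSE4, QDR2 and YMR030W-A, so these sizes are lower bounds and their order is not exact. All 586 genes had mutant cultures that did not overlap the wild-type cultures, which a call on these same culture means nearly requires. Among all genes 58.3% had such cultures, where chance gives 33.3% for a single gene, but genes are not independent and no test was made. The strain level count was 289 without wild-type culture 1 and 1594 without mutant culture 2, and it was 1810 with culture as a random block over all arrays.

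More genes passed in the later part of the course, while some differences were smaller there (CLB1 2.17 up to 142 min and 0.32 after, GAL1 1.81 and 1.32, SNL1 3.63 and 3.08). Up to 142 min 17 genes were higher and 30 lower, and after 142 min 963 were higher and 696 lower. A test of the change itself called 930 genes with a more positive and 772 with a more negative difference in the later part (limma). The strains were compared at equal times although their cycle periods differed. For cycling genes each part can therefore cover different stages of the cycle in the strains, which was not separated from a change in level. After 142 min, stress genes were higher in 15 of 20 members and lower in 1 (17 and 1 adjusted over the list alone), with a median of 1.02 against -0.16 in the earlier part. All 6 other members of the a-specific list besides BAR1 were lower after 142 min, with MFA2 at -3.86 against -0.33 earlier. Ribosome biogenesis genes were lower in 11 of 29 members after 142 min (median -0.26; 12 adjusted over the list alone) against a median of 0.13 earlier. The change was called by camera for 11 lists, and for 0 with an estimated correlation (1 at an unadjusted p under 0.05, smallest adjusted p = 0.761 with an estimated correlation).

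**Figure D2:**
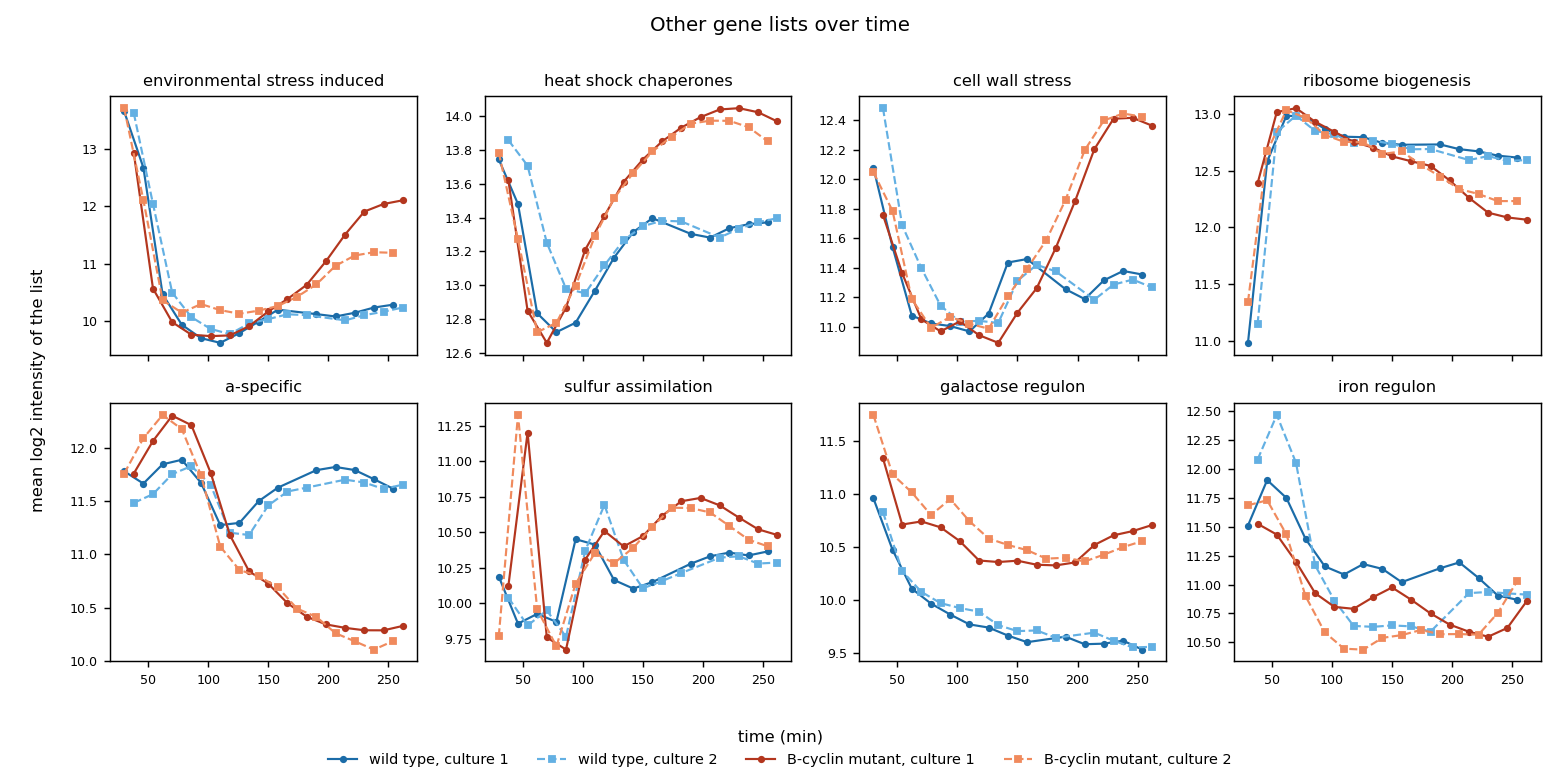
Mean log2 intensity of 8 gene lists of other kinds against time in minutes, with a line for each of the 4 cultures. The stress list falls from 13.65 at 30 min in the wild type to 9.62 at 110 min, and late in the course both mutant cultures lie above both wild-type cultures.

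Most G1/S genes passed the rule for periodic transcription in the mutant. The period of each strain was chosen on these same G1/S genes, which favours their counts over those of other lists. Of the 28 replication and repair genes of G1/S, 27 were periodic in the wild type and the same 27 in the mutant. RNR1, the large subunit of ribonucleotide reductase, had a fitted peak-to-trough of 2.34 ± 0.41 (log2, SE) in the wild type and 2.30 ± 0.46 in the mutant, the cohesin gene MCD1 2.24 ± 0.35 and 2.09 ± 0.37, and POL1 1.91 ± 0.32 and 2.08 ± 0.35. Of the 24 genes of budding, cell wall and regulation, 24 were periodic in the wild type and 18 in the mutant, all 18 shared. They included PCL1 (2.42 and 2.16), TOS6 (2.28 and 2.65) and YOX1 (2.18 and 1.77). All 9 genes of the Mcm1 early cell cycle box were periodic in the mutant and 7 in the wild type, among them SWI4 (1.31 in the wild type and 1.68 in the mutant). The mutant mean of this list reached 11.59 at 78 min and averaged 9.81 in the last part of the course. These calls alone therefore do not show a second rise of equal height. The largest mutant peak-to-trough values also included POL30 (2.44), YBR071W (2.41), the kinase gene KIN3 (2.21), ESC8 (2.19), TOS4 (2.17), CDC21 (2.15) and ALG14 (2.11).

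In 3 other cell cycle lists fewer members passed the rule in the mutant than in the wild type, at periods chosen on the G1/S genes, and the difference in periodicity between strains was not tested. The dynamic range of KAR3, CIN8 and NDD1 was not called different (0.05, 0.03 and 0.07). Nor was that of the histone list (median log2 ratio of SD over time -0.02, camera adjusted p = 0.782), so its lower count does not show a smaller change over time. All 7 measured core histones were periodic in the wild type and 1 in the mutant (HTA1, chosen by the same rule, at 0.87 in the wild type and 0.69 in the mutant). The linker histone HHO1, periodic in the wild type and not called in the mutant, had 1.44 ± 0.25 and 1.21 ± 0.42. Of 13 S phase and spindle genes, 9 were periodic in the wild type and 0 in the mutant, where KAR3 had 1.06 and 0.57, CIN8 0.98 and 0.51, and NDD1 0.98 and 0.74 (limma; in the mutant 1 of the 13 at an unadjusted p under 0.05). Of 21 CLB2 cluster genes, 5 were periodic in the wild type and 1 in the mutant, with HOF1 at 1.45 and 0.04, HST3 at 1.14 and 0.28, and SRC1 at 1.06 and 0.61. The counts of the CLB2 cluster and of the S phase and spindle list depended on the earliest arrays. Without the arrays before 62 min, 20 of the 21 CLB2 cluster genes were periodic in the wild type and 8 in the mutant, and for the S phase and spindle list the numbers were 8 and 8. The histone list changed little, with 8 and 2 of its 8 members against 8 and 1 over all arrays.

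**Figure D3:**
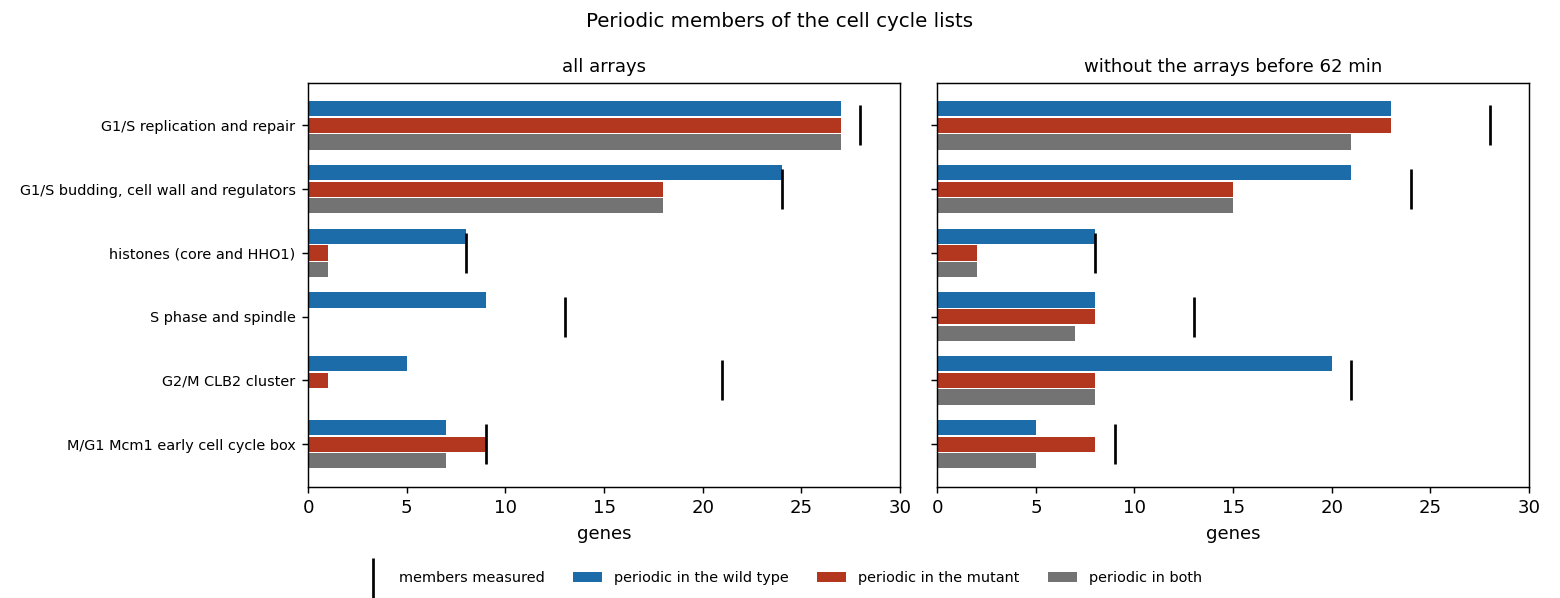
Number of members of 6 cell cycle lists periodic in the wild type, in the mutant and in both, over all arrays (left) and without the arrays before 62 min (right); black marks give the members measured. Over all arrays 27 of 28 replication and repair genes are periodic in both strains, and 8 and 1 of the 8 members of the histone list, which includes HHO1, are periodic in the wild type and the mutant.

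Over all genes, 605 were periodic in the wild type, 357 in the mutant and 242 in both. The shared genes were 40.0% of the wild-type set, and independent sets of these sizes would share 39.6 genes. Across the 242 shared genes, which are not independent replicates, the circular correlation of peak phase was 0.902. The wild-type set also held genes of the stress list, 16 of 20 members against 0 in the mutant (limma; 1 at an unadjusted p under 0.05). MSC1 (2.42), TKL2 (2.29), SOL4 (2.29) and CTT1 (2.26) were among its 10 largest values, and none of these 4 passed without the arrays before 62 min, when 2 of 20 stress genes were periodic in the wild type and 6 in the mutant. Without these arrays the number of wild-type periodic genes was 282. Without wild-type culture 2 it was 0 (limma; 335 at an unadjusted p under 0.05) and without wild-type culture 1 it was 116, while the number of mutant periodic genes was 22 without mutant culture 1 and 158 without mutant culture 2.

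The time between the peaks of G1/S genes was longer in the mutant cultures. The replication and repair list first peaked at 98.5 ± 7.8 min (SD, n = 2) in the wild type and 95.5 ± 7.8 min in the mutant. Its second peak came at 189.5 ± 12 min in the wild type and 240.5 ± 3.5 min in the mutant, and for the budding list at 195.0 ± 5.7 min and 241.0 ± 1.4 min. The Mcm1 list peaked at 83.0 ± 5.7 and 166.0 ± 5.7 min in the wild type and at 78.5 ± 0.7 and 228.5 ± 7.8 min in the mutant. The later mutant peak time marks a low signal. The mutant list mean was highest at 78 min (11.59) and lowest at 166 min (9.63). It averaged 9.81 in the last part of the course, below the 10.10 of the first arrays. The wild-type list averaged 11.09 in that last part. The histones peaked at 114.0 ± 5.7 and 207.0 ± 2.8 min in the wild type and first at 115.5 ± 4.9 min in the mutant, with a later value still rising at the end. The period of the G1/S genes was 97 and 98 min in the wild-type cultures and 141 and 134 min in the mutant cultures, a difference of 40 min. Fitted over both cultures of a strain, as used for the periodic genes, the periods were 102 min in the wild type and 130 min in the mutant, closer together than those per culture. The exact permutation test gave p = 0.333 (two-sided), the smallest that this test gives with 4 cultures, so it cannot pass 0.05 by this test. Alternatives in scaling, gene lists and trend term gave a cycle period difference, from periods per culture, between 30 and 50 min, the longest with a mutant period at the upper limit of the search.

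**Figure D4:**
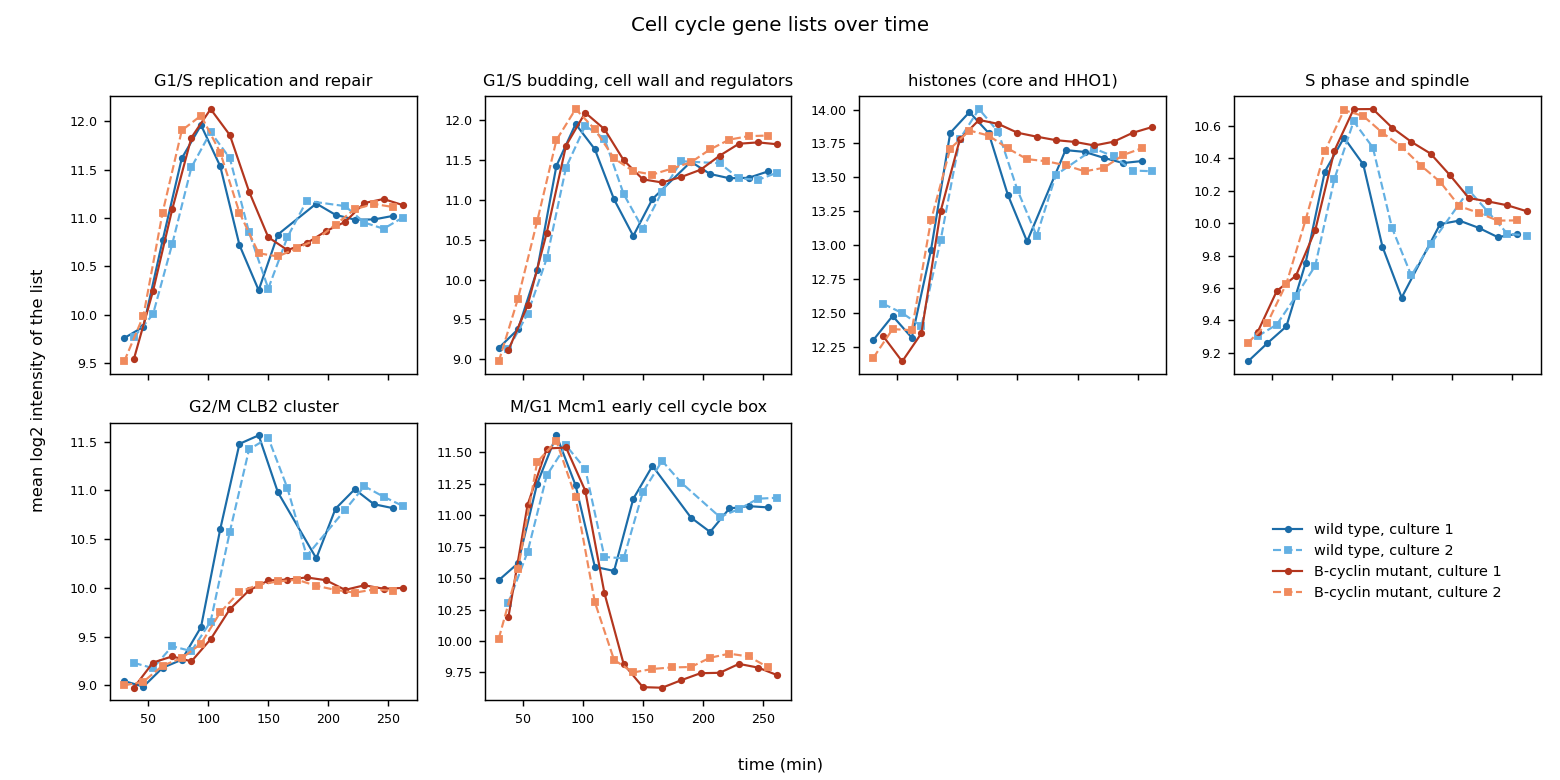
Mean log2 intensity of 6 cell cycle lists against time in minutes, with a line for each of the 4 cultures. The G1/S lists peak near 100 min in both strains and again near 190 min in the wild type and 240 min in the mutant, while the CLB2 cluster reaches 11.56 in the wild type and 10.11 in the mutant.

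The CLB2 cluster of mitotic genes was called downwards in amplitude by camera at the preset correlation, and few of its members passed alone. The median of the log2 ratio of SD over time was -1.03 for the CLB2 cluster (1 of 21 lower; 13 lower adjusted over the list alone). Camera gave an adjusted p of 8.3e-16, and the call was lost with an estimated correlation (adjusted p = 0.495). The replication and repair list (0.16), the Mcm1 list (0.43), sulfur assimilation (0.76), the a-specific genes (0.26) and meiosis and sporulation (0.53) were called upwards. Of the 14 meiosis and sporulation genes 11 averaged below background, so that value is mostly background variation. Ribosome biogenesis (-0.64) and mitochondrial respiration (-0.36) were called downwards. These calls too were lost with an estimated correlation (adjusted p from 0.495 to 0.831 with an estimated correlation), and without the arrays before 62 min the replication and repair list was at -0.07 and ribosome biogenesis at 0.16. The G1/S budding list, with a median of 0.00302 and a mean of -0.04, was not called.

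Among single genes, 8 had a smaller dynamic range in the mutant and 0 a larger one (limma; at an unadjusted p under 0.05, 240 and 278). They were HOF1 (-3.65 ± 0.39), CLB1 (-2.89), the phosphate transporter gene PHO84 (-2.65), DSE4 (-2.57), YMR030W-A (-2.52), YNL046W (-2.41), PCL9 (-2.33) and CLB2 (-2.26). HOF1, DSE4, YMR030W-A, PCL9 and CLB2 averaged below background in the mutant, where their SD over time is that of background, so their ratios and order are not exact. The dynamic range count was 1 without mutant culture 2 and 0 without mutant culture 1, wild-type culture 1 or wild-type culture 2 (514, 247 and 298 at an unadjusted p under 0.05). It was 142 without removal of the time trend, of which 110 were higher, and PHO84 was at 1.35 without the arrays before 62 min. The shape of the time course was called different between strains for 4018 genes (73.7%; limma F-test of the interaction), among them 562 of the 605 genes periodic in the wild type. This test treats arrays as independent given the model, with 2 cultures per strain, so its p-values can be too small. It does not model shifts in time between cultures of a strain, which aligned best at -10 min in the wild type and 4 min in the mutant.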

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

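The tests of other splits of the cultures and of array scaling were set before the results they measure were seen, and all other tests of explanations in this part, listed with each pattern, were chosen after.

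The strain difference changed between the times up to 142 min and the times after them for 1702 genes by a limma test of the change itself, 930 with a more positive and 772 with a more negative difference later. Strains were compared at equal times although their cycle periods differed, and for cycling genes the timing of the cycle was not separated from level. Among named genes the change was 2.31 for GPM2, 1.53 for APE1, 1.36 for HXT2, 1.31 for TIR3, 0.75 for ARG4, 0.64 for UBC13, 0.57 for CLB5 and 0.50 for HIS2. It was -3.53 for MFA2, -2.97 for DSE4, -2.16 for MCM7, -1.85 for CLB1, -1.77 for CLB2, -1.69 for YGP1, -1.49 for HOF1, -1.37 for YMR030W-A, -0.55 for SNL1 and -0.49 for GAL1. Camera called the change of 11 lists, of which 10 are given here, with medians of 1.06 for the stress list, 1.03 for cell wall stress, 0.54 for heat shock chaperones and 0.24 for amino acid biosynthesis. The falling medians were -0.24 for G1/S replication and repair, -0.27 for the CLB2 cluster, -0.43 for ribosome biogenesis, -0.49 for the phosphate regulon, -1.01 for the Mcm1 list and -1.18 for the a-specific list. With an estimated correlation camera called 0 lists, 1 of the 24 had an unadjusted p under 0.05, and the smallest adjusted p was 0.761 with an estimated correlation.

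Among 3683 probe sets without a gene name, which the comparisons of the 5449 genes do not use, 12 were above the wild type and above background in the mutant and 11 were lower (limma). The control probe sets for the 3′ and middle parts of URA3 differed by 1.42 and 1.30 (adjusted p = 0.0029 and 0.0066), while that for its 5′ part was at -0.47 (adjusted p = 0.04). Of the reporter probe sets, 2 differed by 0.90 and 1.55 and another by -0.53 (adjusted p = 0.047).

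SNL1, BAR1 and YIL014C-A lay below background on all wild-type arrays and above it on all mutant arrays. Array scaling is argued against, since the smallest difference of the 3 genes under quantile normalisation and median centring was 2.40, and a higher background on the mutant arrays is argued against by a background difference of -0.0472. The wild-type strain is labelled bar1, and a candidate explanation is a disruption of BAR1 there that reaches SNL1 and YIL014C-A, since the measured genes next to the 3, VID28 and MNT3, had a lowest value of 10.84 on any wild-type array. The extent of that disruption was not analysed here, all 3 genes were above background on 30 of 30 mutant arrays, and VID28 was itself lower in the mutant (-1.32 ± 0.08).

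CLB1 was high and nearly flat in the mutant, and CLB5 and CLB6 gave signal there. Cross-hybridisation of the CLB5 probe set with a transcript at the same level in both strains is argued against by the CLB5 difference of 1.03. That difference was known when the test was chosen. Cross-hybridisation with a transcript that itself differs between the strains was not tested and stays open. Transcription of CLB1 from its own promoter, regulated as in the rest of the CLB2 cluster, is argued against by the first 2 arrays. CLB1 was higher there in the mutant by 3.58 (gap between the nearest cultures 3.29). The differences of the cluster's other genes lay between -0.53 (HOF1) and 0.23 (BUD8). The GAL1 promoter construct stays open as a source, since from the first 2 arrays to the last part of the course CLB1 changed by -0.62 in the mutant (-0.52 and -0.73 per culture) and GAL1 by -1.46 and -1.62, but GAL1 changed by -1.13 and -0.83 in the wild type too, and 306 genes (5.62%, CLB1 included) fell at least as much as CLB1 in both mutant cultures. Transcription of part of the disrupted CLB5 and CLB6 loci stays open, since CLB6 averaged 9.99 in the mutant and probe positions were not used here.

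The environmental stress list was higher in the mutant late in the course. Array scaling is argued against, since its smallest median difference after 142 min under quantile normalisation and median centring was 1.02. A single mutant culture is argued against, since from 230 min on the lower mutant culture exceeded the higher wild-type culture by 0.93. Ageing in both strains alike stays open, since the rises from 78 to 110 min to the last part were 2.27 and 0.98 in the mutant cultures and 0.51 and 0.20 in the wild-type cultures, an excess of 1.27 with a pooled SD of 0.66. An effect of the cyclin disruptions named in the label also stays open and was not tested apart from strain.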

How the results depend on the processing

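The fits without the arrays before 62 min and without 2 arrays of outlying background (wild-type culture 2 at 38 min, mutant culture 1 at 86 min) were chosen after seeing the data. A lone culture in a strain was assumed to vary like the others. The strain level count of 586 was 47 up to 142 min, 1659 after 142 min, 1810 with culture as a random block, and 289 to 1594 with a culture left out. The dynamic range count of 8 was 20 with quantile normalisation (4 higher, 16 lower), 5 with median centring, 2 without dim genes, 142 without removal of the trend (110 higher, 32 lower), 0 without the arrays of outlying background (limma; 76 at an unadjusted p under 0.05), and 0 to 1 with a culture left out (247 to 1023 at an unadjusted p). The 605 wild-type periodic genes became 261 with a second harmonic, 1896 with no fold rule, 219 at 2-fold, 262 at an adjusted p under 0.01, 282 without the early arrays, 343 without the arrays of outlying background, and 0 to 116 with a culture left out (335 and 390 at an unadjusted p). The 357 mutant periodic genes became 741 with the period from all 7 cell cycle lists, 0 with the wild-type period (389 at an unadjusted p), 1236 with no fold rule, 118 at 2-fold, 179 at an adjusted p under 0.01, and 22 to 158 with a culture left out. The 242 wild-type periodic genes also periodic in the mutant became 418 (71.8%) with all 7 lists, 0 with the wild-type period (330 at an unadjusted p), 120 with a second harmonic, 752 with no fold rule, 86 at 2-fold, 102 at an adjusted p under 0.01, 160 (46.6%) without the arrays of outlying background, and 0 to 93 with a culture left out (219 at an unadjusted p in the fit with 0). The cycle period difference of 40 min was 35 with quantile normalisation, 50 with all 7 lists, 30 with no linear time term and 45.5 without the early arrays. With all 7 lists the mutant period was 160 min, the upper limit of the search, so the 3 values from those lists rest on a limited period. The strain by time interaction count of 4018 lay between 3086 and 4177 in all fits tried. With an estimated correlation camera called 0 of the lists in gene list level and 0 in gene list dynamic range (3 and 1 at an unadjusted p), against 12 and 9. Deviations of cultures paired by replicate number correlated at -0.056 across genes, and those paired by sampling grid at 0.056, so neither pairing was strong in this measure. With 2 cultures per strain these values mirror each other by construction. Peak times did go with the grid. The replication and repair list first peaked at 93 and 90 min on the grid from 30 min, and at 104 and 101 min on that from 38 min. With replicate number as a block the strain level count was 741, dynamic range 0 (454 at an unadjusted p), and the lists 11 and 10.

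Up to 142 min the level differences of opposite sign among genes named for their level were APE1 -0.15, DSE2 0.29, NOG2 0.0294, HSP42 -0.0137, HSP12 -0.0812, TSL1 -0.0114, HSP104 -0.0675, HSP82 -0.11 and STI1 -0.00184, and among called genes named for periodicity DSE1 0.64, TKL2 -0.41, MSC1 -0.17 and CTT1 -0.11. Without the early arrays, the dynamic range of PHO84 was 1.35, and the gene list dynamic range of G1/S replication and repair was -0.0725, the gene list dynamic range of phosphate regulon 0.54 and the gene list dynamic range of ribosome biogenesis 0.16. Of 1356 alternative values of named genes' levels, 1234 kept direction and side of the threshold, 92 lost the call, 21 gained it and 9 reversed, and values uncalled in both fits count as kept whatever their sign (6 changed it). For dynamic range of genes 527 of 607 kept both, for list levels 81 of 96, for list dynamic range 76 of 96, for wild-type peak-to-trough 319 of 413 and for mutant peak-to-trough 155 of 170. Fits with a part of the arrays or a stricter rule hold fewer arrays or genes by construction, and otherwise the cause was not tested. Signal over background limits what can be seen of genes that do not average above 9.06, and 4853 of 5449 do.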

Other observations

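The windows of time and the neighbouring genes given here were chosen after the data were seen, with no planned test of them, while the tests of other splits of the cultures were set before.

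Both strains began with high stress transcripts and lower ribosome biogenesis transcripts after elutriation. On the first array of each culture the environmental stress list averaged 13.64 ± 0.02 (SD, n = 2) in the wild type and 13.32 ± 0.55 in the mutant, and over 78 to 110 min it was at 9.86 ± 0.15 and 9.98 ± 0.33. Ribosome biogenesis genes were at 11.07 ± 0.12 and then 12.86 ± 0.03 in the wild type, and at 11.87 ± 0.74 and then 12.86 ± 0.03 in the mutant. Sulfur assimilation genes had a brief high value on the second array of both mutant cultures, 11.20 at 54 min and 11.32 at 46 min, while the highest wild-type value was 10.69 at 118 min. These changes over time were not tested.

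Of the 22 measured direct neighbours of the 13 targeted and label genes, 9 were called in level, against 586 of all 5449 genes. Of the 9, SNL1, YIL014C-A and GAL10 are in the report. ATG38, next to CLB4, was at -1.11 ± 0.09 and PNP1 on its other side at -0.62 ± 0.09. YSC83, next to ARG4, was at 0.94 ± 0.08, and HSL1, next to APE1, at 0.65 ± 0.08 and GFA1 on its other side at -0.37 ± 0.09. YCL021W-A, next to LEU2, was at 0.50 ± 0.11 (limma, adjusted p from 0.00059 to 0.043 for these 6).

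The 4 cultures can be split into pairs in 3 ways, too few for a share under 0.05. The split by strain gave 586 genes in strain level and the highest other 0 (limma), 8 genes in dynamic range and the highest other 0, and 4018 genes in the strain by time interaction and the highest other 40. In each case 1 of the 3 splits gave as many genes, the split by strain itself. In the other splits each pair held a wild-type and a mutant culture. A strain difference then adds to the spread within pairs and lowers the count, so these counts are not a rate of false calls.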
